A study of Mus musculus with 26 samples.

How the data were processed

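The series holds 26 mouse samples. Of these, 20 are promoter arrays hybridised with chromatin immunoprecipitates, and 6 are one-colour expression arrays. The immunoprecipitates were made with antibodies to trimethylated lysine 4 of histone H3 (H3K4me3), a mark of active and poised promoters, and to trimethylated lysine 27 (H3K27me3), a mark deposited by Polycomb proteins. Each mark was measured in 5 cell lines: the embryonic stem (ES) cell lines E14 and V6.5, a male and a female line of mouse embryonic fibroblasts (MEF1 and MEF2), and 1 line of induced pluripotent stem (iPS) cells. Each line and mark took a set of 2 arrays that carry different promoters, so a line is 1 replicate per mark. Expression was measured on 2 arrays each of feeder-dependent V6.5 ES cells, female MEFs and iPS cells. Nothing in the labels says that the second array of a pair came from a separate culture, so p-values for expression measure only the spread between these arrays.

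Per the labels, immunoprecipitated DNA and input DNA were amplified and labelled with Cy5 and Cy3. The labelling text of the MEF H3K27me3 arrays names Cy3 for the immunoprecipitate while their label field names Cy5. The probe values of those arrays correlated positively with those of the other H3K27me3 arrays, so the label field was followed. The deposited scanner files give intensity per spot, background-subtracted, spatially detrended and linearly dye-normalised within the array by Agilent Feature Extraction (version 9.1.3.1 for the promoter arrays and 9.5.1.1 for the expression arrays, per the file headers). The deposited value tables of the promoter arrays hold the log10 ratio of red over green processed signal. The deposited value table of the expression arrays holds the processed signal as intensity.

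For the promoter arrays, log2 of Cy5 over Cy3 was computed from the deposited processed intensity and each array was centred on the median of its non-control probes. A promoter's value was the mean over the probes within 1000 bp on either side of the transcription start, which was placed between the probes that the files label as promoter and those that they label as inside the gene. At least 3 probes and a gap of at most 1000 bp at the start were required, and 15174 promoters with a median of 10 probes were kept. Left out were 1275 genes without both kinds of probe, 135 with several starts, 419 with a wider gap and 51 with too few probes. Of the promoters kept, 2798 face a divergent gene and 44 share all probes with another gene. Coordinates are those of the array files, whose genome build is not given in the sources used here. Gene symbols, 3305 of which were updated, were matched to a table of current names from GRCm38.p6, used for names only.

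For expression, log2 of the deposited processed intensity minus each array's 75th percentile was used, spots of one probe were averaged, and probes well above background on both arrays of at least 1 group were kept (25324 of 41174). A gene was represented by its probe with the highest mean, and 17109 genes were tested. The deposited value table and the scanner files disagree about the samples: the values in the ES columns are those of the scanner files filed under MEF, and the reverse, on both slides. The value table was followed, and its MEF columns hold high Xist, the RNA of the inactive X chromosome, and low Pou5f1. The scanner file filed under the iPS duplicate stops after 28350 of 45018 spots and matches no column, so that array took its background limits from the other iPS array. Where a group lay below the lowest signal well above background, or at saturation, the fold is given as a bound ("at least").

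Comparisons were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with the data.table package, version 1.17.8. All 6 expression arrays shared 1 fit with 3 residual degrees of freedom, and the 5 lines of each mark shared 1 fit with 2, in which the single iPS line was assumed to vary like the ES and MEF lines. A call needed a Benjamini-Hochberg adjusted p under 0.05 over all genes or promoters of the comparison, and for expression also a change of at least 2-fold. Promoters were also counted where both ES lines lay at least 1 log2 unit above, or below, both MEF lines. A promoter counted as marked at a log2 ratio of at least 1. Shares carry exact binomial 95% intervals, which cover counting error only. The X chromosome was compared with 10000 random autosomal lists of the same size. For arrays, the number of arrays limits the precision.

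The tests, the alternatives, 18 gene lists and the rule for naming genes were fixed before the data were examined. The lists hold the pluripotency network, the reprogramming factors, fibroblast and mesenchymal genes, epithelial junction genes, Hox clusters, developmental regulators outside Hox, and genes of extraembryonic endoderm, trophoblast, nerve, blood and macrophages, and the germ line. The others hold imprinted genes, cell cycle genes, cell cycle inhibitors and p53 targets, chromatin and DNA methylation genes, interferon response genes, the X inactivation centre and housekeeping genes. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 18 lists within a comparison. No list call at an adjusted p under 0.05 held in any of the 9 comparisons when the correlation was estimated instead. Named genes are, for expression, up to 10 called genes with the largest fold in each direction that have a symbol other than a clone, gene model or accession number, and the 8 called promoters with the largest difference in each direction for each mark. Where no promoter was called, they were taken among those with the consistent 2-fold difference between ES and MEF, and members of the lists may be named as well. Genes with near-identical copies are named as uncertain, and the values of some list members are not reported here.

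The fits were tested on simulated data in which 200 of 25243 expression probes, or of 15174 promoters, were changed in the MEF group. With so few changed, the adjusted p is harder to pass than in the data, where far more genes were called. The recoveries below are therefore not the power of the real comparisons. In the MEF against ES comparison of 6 simulated expression arrays, 2 of 67 changes of 2 log2 units, 29 of 67 changes of 4 units and 51 of 66 changes of 6 units were recovered, with 1 false call. For H3K4me3, 0 of 100 changes of 1 unit and 47 of 100 changes of 2 units were recovered between MEF and ES, and 0 of either between iPS and MEF. For H3K27me3, 43 and 76 of 100 were recovered between MEF and ES, with 6 false calls, and 3 and 60 between iPS and MEF.

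Alternatives for the promoter arrays were normexp background correction with an offset of 50, division of each array by its median absolute deviation, the mean over all probes of a gene, the highest mean of 3 neighbouring probes, the deposited value tables, a limit of 0.58 log2 units, the turned sign of the MEF H3K27me3 arrays, other lines to choose the promoters, and leaving out each line. Alternatives for expression were normexp, quantile normalisation, no filter on dim probes, adjusted p alone, the mean over all kept probes, the slide as a block and leaving out each array. Chosen after seeing the data were array weights, the scanner files as filed, the ES and iPS arrays alone, positions and lists without the MEF duplicate array, and the 3 alternatives for X-linked expression. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.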

Results

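Promoter H3K4me3 and H3K27me3 were measured in 2 ES lines, 2 MEF lines and 1 iPS line on 20 arrays, and RNA was measured on 6 arrays, 2 each of ES cells, MEFs and iPS cells. Between 93.57% and 99.96% of the spots of a promoter array were well above background in each channel. The median absolute deviation of the log2 ratio was 0.291 and 0.289 on the E14 H3K27me3 arrays and ran from 0.417 to 0.712 on the other H3K27me3 arrays. On the expression arrays, the 75th percentile of the signal ran from 358.2 to 838. Between 46.4% and 58.9% of the probes were well above background on 4 expression arrays with flags and 86.7% on the MEF duplicate, whose median signal was 306.6 against 34.9 on the other MEF array. Log2 signals correlated at 0.978 between the ES arrays, 0.992 between the iPS arrays and 0.781 between the MEF arrays. The series design asks how far iPS cells resemble ES cells, and how far MEFs, in histone marks and expression.

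Expression in MEFs against ES cells sets out the distance between fibroblasts and the pluripotent state. Of the prepared lists, 31 of 33 members of the pluripotency network were lower in MEFs and 31 of 36 fibroblast genes higher. Esrrb, a nuclear receptor of the pluripotency network, was at least 589-fold lower in MEFs, with levels of 5.51 ± 0.19 in ES cells and -4.67 ± 0.44 in MEFs (log2 relative to the 75th percentile, SD, n = 2 arrays). Lum, the matrix proteoglycan lumican, was at least 495-fold higher in MEFs, from -5.27 ± 0.12 to 4.63 ± 0.46. In limma, 5844 of 17109 genes were called, 2739 higher and 3105 lower in MEFs, a balance that turned without the filter on dim probes (1855 and 1378) and with the slide as a block (2185 and 1826).

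Among the other genes with the largest folds in MEFs, Saa3, an acute-phase protein, was 895-fold higher and Dcn, the collagen-binding proteoglycan decorin, 316-fold. The chemokines Cxcl5 and Ccl8 were at least 151-fold and 66.1-fold higher, Ptx3, a pentraxin of innate immunity, at least 237-fold, Serpina3g, a protease inhibitor, at least 255-fold, and Cp, the copper carrier ceruloplasmin, at least 107-fold. Cbr2, a carbonyl reductase, was at least 124-fold higher and Xist at least 191-fold (adjusted p = 0.000694). Toward ES cells, Sox2 and Nanog, core transcription factors of pluripotency, were at least 194-fold and 131-fold lower in MEFs. Dppa5a was at least 690-fold lower, Tex19.1, expressed in pluripotent and germ cells, at least 308-fold, Fbxo15, an F-box gene used as an ES cell marker, at least 361-fold, and Tdh, threonine dehydrogenase, at least 512-fold. Aire was at least 267-fold lower, Zfp42 427-fold and Phlda2, an imprinted gene, 384-fold. The MEF arrays differed widely for Zfp42 (-3.21 ± 2.47, SD, n = 2), Phlda2 (-3.66 ± 2.16), Tdh (-2.28 ± 1.94) and Dppa5a (-2.16 ± 1.48), so these folds and bounds are rough. Adjusted p for these genes lay between 0.000593 and 0.00147.

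The pluripotency network fell as a group in MEFs: 31 of 33 members were lower and 0 higher (32 called when adjusted over the list alone). The list's adjusted p was 3.37e-16, against an adjusted p = 0.197 with an estimated correlation, and its median was -6.47, or -5.12 with bounds in place of fitted values. Tfcp2l1 was 243-fold lower, Dppa4 218-fold, Dppa3 171-fold and Pou5f1, the gene of Oct4, 165-fold (adjusted p = 0.00386), with MEF arrays at -4.64 and -0.63. The MEF arrays lay apart for Tfcp2l1 (SD 1.77), Dppa4 (2.59) and Dppa3 (1.93) as well, with 1 of 2 well above background, so these folds are rough. Klf2 (-0.30, adjusted p = 0.621) and Eras (-3.53, adjusted p = 0.0822) were not called. Fibroblast and mesenchymal genes rose: 31 of 36 were higher and 0 lower (33 adjusted over the list alone, adjusted p = 7.46e-15, adjusted p = 0.311 with an estimated correlation, median 3.59). The growth factor receptor Pdgfra was 44.2-fold higher, Postn 43.1-fold, Twist2 40.8-fold and the collagen gene Col5a2 36.1-fold. Fn1 (1.32), Vim (at least 2.49-fold, saturated in MEFs), Ccn2 (-0.17) and Cdh11 (-0.57) were among those not called.

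Hox genes, which set position along the body axis, also rose, with 23 of 29 members higher and 0 lower (23 adjusted over the list alone, adjusted p = 1.52e-10, adjusted p = 0.197 with an estimated correlation, median 3.85). Hoxc6 was 30.7-fold higher, Hoxa9 23.6-fold and Hoxb4 19.9-fold. Blood and macrophage genes rose in 9 of 11 members, with Laptm5 lower (10 adjusted over the list alone, adjusted p = 1.24e-05, adjusted p = 0.197 with an estimated correlation, median 4.42). Among them Lyz2, lysozyme, was 99.8-fold higher and the macrophage receptor Csf1r 29.7-fold. Interferon response genes rose in 9 of 14 members and fell in 0 (10 adjusted over the list alone, adjusted p = 2.49e-05, adjusted p = 0.197 with an estimated correlation, median 2.60), with Mx2 16.8-fold and Isg15 14.9-fold higher.

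Cell cycle genes fell in MEFs in 23 of 24 members, all but Tyms (24 adjusted over the list alone, adjusted p = 1.11e-11, adjusted p = 0.197 with an estimated correlation, median -3.27). Mybl2 was 87.9-fold lower, the replication factor Mcm5 28.9-fold and Mki67 10.2-fold. Chromatin and DNA methylation genes fell in 21 of 27 members and rose in 1 (22 adjusted over the list alone, adjusted p = 6.38e-07, adjusted p = 0.197 with an estimated correlation, median -2.33). The methyltransferase genes Dnmt3l and Dnmt3b were 109-fold and 99.1-fold lower, and the Polycomb genes Cbx7 and Jarid2 83.9-fold and 29.3-fold. Epithelial junction genes fell in 9 of 16 members and rose in 0 (13 adjusted over the list alone, adjusted p = 5.91e-06, adjusted p = 0.412 with an estimated correlation, median -4.51), with the keratin Krt8 142-fold and E-cadherin, Cdh1, 45.3-fold lower (MEF SD of Cdh1 1.37). Germ line genes fell in 5 of 14 members and rose in 0 (5 adjusted over the list alone, adjusted p = 0.000855, adjusted p = 0.412 with an estimated correlation, median -2.54), among them Rhox5, 54.2-fold, and Dazl, 16.5-fold (MEF SD 1.70). With bounds in place of fitted values, the medians were 3.35 for Hox, 4.09 for blood, 2.58 for interferon, -3.28 for cell cycle and -2.47 for germ line genes, and 3.59 for fibroblast, -2.33 for chromatin and -4.51 for epithelial genes.

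The remaining lists did not pass in MEFs against ES cells. Adjusted p was 0.0535 for the reprogramming factors (2 of 4 lower), 0.0824 for trophoblast (3 of 9 lower, and 0.00148 without the MEF duplicate array), 0.24 for imprinted genes (6 of 21 higher, 3 lower) and 0.276 for neural genes (1 of 8 higher, 4 lower). It was 0.338 for housekeeping genes, 0.736 for the X inactivation centre, 0.82 for developmental regulators (8 of 34 higher, 7 lower), 0.948 for cell cycle inhibitors and p53 targets and 0.951 for extraembryonic endoderm. The median and the mean differed in sign for the X inactivation centre (-0.37 and 1.17) and extraembryonic endoderm (0.58 and -0.46). The median over all genes was -0.123 with the 75th percentile, -0.013 with normexp and -0.37 with quantile normalisation, and the lists that passed kept their sign relative to it under each. Relative to that median, normexp took pluripotency from -6.35 to -4.25, blood from 4.54 to 2.33, Hox from 3.98 to 2.17, epithelial genes from -4.39 to -2.96 and germ line genes from -2.42 to -1.13. Without the first ES array 2551 genes were called and without the first MEF array 9746, and the scanner files taken as filed turned the direction.

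iPS cells against MEFs tests what separates the reprogrammed cells from fibroblasts. The MEF arrays are those compared with ES cells above, so both comparisons share their spread. Nanog was at least 122-fold higher in iPS cells, at 3.24 ± 0.03 against -5.71 ± 0.61 in MEFs (SD, n = 2). Ptn, the secreted growth factor pleiotrophin, was 1210-fold lower, at -3.57 ± 0.39 against 6.67 ± 0.68. In limma, 6090 genes were called, 3160 higher and 2930 lower in iPS cells, a balance that turned with normexp (2182 and 2475), without the filter on dim probes (1532 and 2244) and with the slide as a block (955 and 1372).

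Also higher in iPS cells were Tex19.1 (at least 813-fold), Fbxo15 (at least 550-fold), Zfp42 (601-fold), Esrrb (at least 297-fold), Dppa5a (at least 429-fold) and the glucose transporter gene Slc2a3 (496-fold). The spread in MEFs was wide for Zfp42 (SD 2.47), Slc2a3 (SD 1.70) and Dppa5a (SD 1.48). Trap1a, a tumour rejection antigen gene on the X chromosome, was at least 336-fold higher, Bex2 at least 243-fold and Xlr5d at least 211-fold. Also lower were Saa3 (926-fold), Dcn (605-fold), Lum (at least 697-fold), Serpina3g (at least 359-fold), Cbr2 (at least 174-fold), Cp (at least 150-fold), Rnf150 (at least 71.5-fold) and the chemokines Cxcl5 (at least 213-fold) and Ccl6 (at least 119-fold). Adjusted p for these genes lay between 0.000335 and 0.000969.

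Of the pluripotency network, 30 of 33 members were higher in iPS cells than in MEFs (31 adjusted over the list alone, adjusted p = 1.03e-14, adjusted p = 0.261 with an estimated correlation, median 5.86). Fibroblast genes were lower in 32 of 36 members (33 adjusted over the list alone, adjusted p = 6.19e-17, adjusted p = 0.305 with an estimated correlation, median -4.55). Hox genes were lower in 23 of 29 and higher in 1 (24 adjusted over the list alone, adjusted p = 4.01e-11, adjusted p = 0.27 with an estimated correlation, median -4.75). Cell cycle genes were higher in 22 of 24 (23 adjusted over the list alone, adjusted p = 4.01e-11, adjusted p = 0.278 with an estimated correlation). Chromatin genes were higher in 17 of 27 and lower in 2 (19 adjusted over the list alone, adjusted p = 1.86e-05, adjusted p = 0.278 with an estimated correlation). Epithelial genes were higher in 11 of 16 (13 adjusted over the list alone, adjusted p = 6.41e-06, adjusted p = 0.335 with an estimated correlation), and germ line genes in 9 of 14 (11 adjusted over the list alone, adjusted p = 3.34e-05, adjusted p = 0.335 with an estimated correlation). Blood genes were lower in 9 of 11 (9 adjusted over the list alone, adjusted p = 4.93e-06, adjusted p = 0.278 with an estimated correlation), and interferon genes in 9 of 14 (11 adjusted over the list alone, adjusted p = 0.000294, adjusted p = 0.278 with an estimated correlation). With bounds in place of fitted values, the medians were 5.59 for pluripotency, -4.54 for fibroblast and -3.84 for Hox genes.

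Against MEFs, adjusted p was 0.0528 for trophoblast (0.0012 without the MEF duplicate array), 0.135 for imprinted genes, 0.138 for extraembryonic endoderm, 0.182 for the reprogramming factors, 0.271 for developmental regulators and 0.705 for housekeeping genes. It was 0.89 for cell cycle inhibitors and p53 targets, 0.919 for neural genes (median -0.44, mean 0.03) and 0.954 for the X inactivation centre (median 0.68, mean -0.23). The median over all genes was 0.133 with the 75th percentile, -0.109 with normexp and 0.45 with quantile normalisation. With the slide as a block 2327 genes were called, without the iPS duplicate array 2695 and without the first MEF array 9759.

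iPS cells against ES cells asks how close the reprogrammed cells came to the pluripotent reference. In the fit of all 6 arrays limma called 40 of 17109 genes, 25 higher and 15 lower in iPS cells, with 2733 at an unadjusted p under 0.05, and in a fit of the ES and iPS arrays alone 2859, 1408 higher and 1451 lower. Xlr5d, Xlr3c and Xlr4b of the X-linked Xlr family and the clone 1700013H16Rik had the largest higher fitted differences, and the lower genes included the Y-linked Eif2s3y. Xlr5d was at least 326-fold higher, at 4.03 ± 0.05 in iPS cells and -5.98 ± 0.03 in ES cells (SD, n = 2, adjusted p = 0.00221). Eif2s3y, a translation initiation factor subunit encoded on the Y chromosome, was 60.9-fold lower, at -4.17 ± 0.03 against 1.76 ± 0.43 (adjusted p = 0.0217).

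Xlr3c was 564-fold and Xlr4b 253-fold higher in iPS cells, and Nxf3, an X-linked gene of the RNA export factor family, at least 49.7-fold. X-linked genes known by clone or model numbers also rose, with 1700013H16Rik at least 203-fold, Gm5128 at least 64.9-fold, Gm364 at least 36.6-fold, 1700080O16Rik at least 30.8-fold and Gm9 98.7-fold higher. Prame (at least 6.43-fold), Magea1 (at least 8.1-fold) and Magea6 (at least 5.47-fold), genes known from testis and tumours, were higher as well. The Xlr, Mage and Prame genes have near-identical copies, so which copy gave the signal is uncertain. Creg2 was at least 13.5-fold, Txlnb at least 5.68-fold and the aminopeptidase gene Xpnpep2 at least 4.53-fold higher. Lower in iPS cells were Afm, the plasma protein afamin (at least 16.5-fold), Cubn, the endocytic receptor cubilin (28.7-fold), and Wnt3a, a signalling protein (at least 6.76-fold). Ifi27l2b was at least 6.3-fold, the ribosome biogenesis gene Rrp7a 9.27-fold and the potassium channel gene Kcnh8 at least 3.81-fold lower. Adjusted p for these genes lay between 0.0074 and 0.0488.

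In the fit of all 6 arrays the pluripotency network gave no calls between iPS and ES cells (0 of 33 called, 0 adjusted over the list alone, adjusted p = 0.515, median -0.32). That fit takes in the spread of the MEF pair, so the lack of calls does not show equal levels. Levels in ES and iPS cells were 0.76 and -1.30 for Foxd3, 5.50 and 4.17 for Rif1, 1.11 and 2.32 for Tcl1, and 3.18 and 4.35 for Zfp296. Pou5f1 differed by 0.07 (adjusted p = 0.984), Nanog by -0.10 (adjusted p = 0.947), Zfp42 by 0.49 (adjusted p = 0.856), Sox2 by -0.71 (adjusted p = 0.513) and Esrrb by -0.99 (adjusted p = 0.319). Fibroblast genes were lower in iPS cells as a list, with 0 of 36 called (6 adjusted over the list alone, adjusted p = 5.42e-07, adjusted p = 0.634 with an estimated correlation, median -0.93). Zeb2 (at least 5.87-fold lower, adjusted p = 0.076), Col1a1 (-2.49, adjusted p = 0.0919) and Acta2 (-2.38, adjusted p = 0.0949) had large differences. Genes of extraembryonic endoderm, the lineage of the yolk sac, were lower as a list, with 0 of 11 called (8 adjusted over the list alone, adjusted p = 0.00119, adjusted p = 0.501 with an estimated correlation, median -1.59). Dab2 differed by -3.35 (adjusted p = 0.0555), Gata6 by -2.85 (adjusted p = 0.0688) and Foxa2 by -2.65 (adjusted p = 0.0919), while Afp was at least 3.94-fold higher (adjusted p = 0.0875).

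Hox genes were lower as a list, with 0 of 29 called (2 adjusted over the list alone, adjusted p = 0.0165, adjusted p = 0.634 with an estimated correlation, median -0.86). With bounds in place of fitted values the median of the Hox list was -0.71, and without the MEF duplicate array its adjusted p was 0.0616. The filter also keeps genes well above background in MEFs alone, and such members enter the list test and median with values near background in both groups. Germ line genes were higher as a list, with 0 of 14 called (1 adjusted over the list alone, adjusted p = 0.0179, adjusted p = 0.634 with an estimated correlation, median 0.91). Sohlh2 differed by 2.98 (adjusted p = 0.16) and Taf7l by 2.37 (adjusted p = 0.0953). The other lists had 0 called members. Adjusted p was 0.0971 for chromatin genes, developmental regulators, neural genes and the X inactivation centre, 0.137 for blood, 0.201 for the reprogramming factors and 0.657 for trophoblast. It was 0.794 for cell cycle, cell cycle inhibitors, epithelial and housekeeping genes, 0.842 for imprinted genes and 0.908 for interferon genes, whose median was -0.03 and mean 0.15. Called members adjusted over the list alone numbered 8 among developmental regulators, 6 among interferon genes and 4 among neural genes.

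The count of 40 rested on the spread of the MEF pair, which enters the shared fit: without either MEF array 2859 genes were called and without either ES array 0, with 2315 and 1229 at an unadjusted p under 0.05. Normexp gave 113 calls, quantile normalisation 21, the slide as a block 137 (122 higher and 15 lower) and no filter on dim probes 0.

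Of the 5844 genes called between MEFs and ES cells, 5140 lay nearer ES cells in the iPS arrays (88%, exact binomial 95% interval 87.1 to 88.8). The median position was 0.96 on a scale with MEF at 0 and ES at 1. Where genes were chosen on one array of each group and placed on the other, 75.3% and 76.1% lay nearer ES cells.

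**Figure D1:**
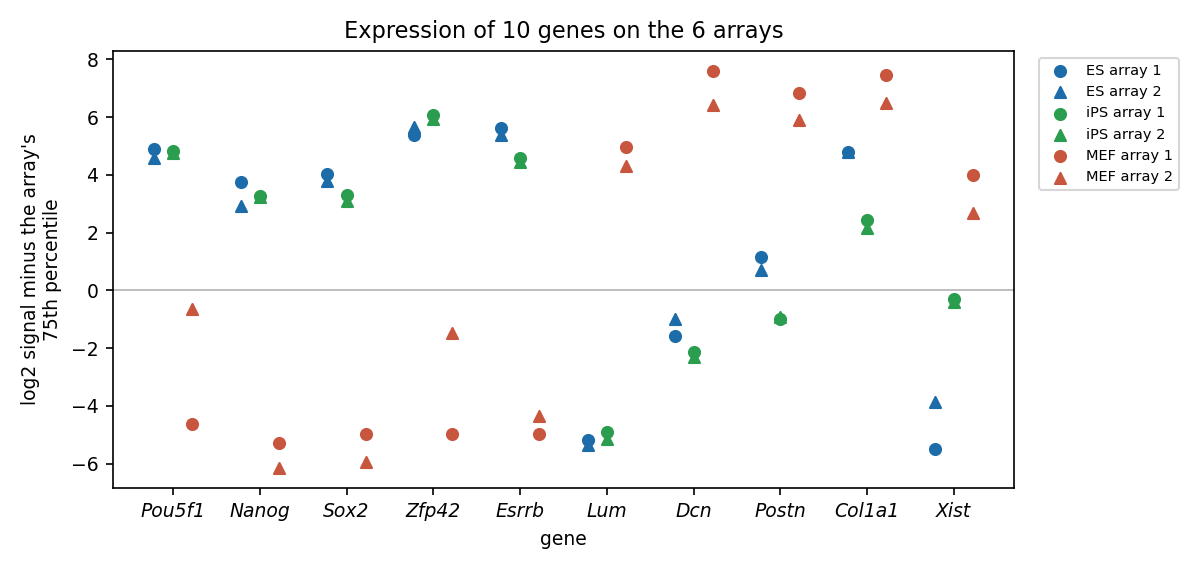
Log2 signal minus each array's 75th percentile (vertical axis) of 10 genes (horizontal axis) on the 6 expression arrays, coloured by ES cells, MEFs and iPS cells, with a circle for array 1 and a triangle for array 2 of each group. Nanog lay at 3.75 and 2.92 on the ES arrays, 3.26 and 3.22 on the iPS arrays and -5.28 and -6.15 on the MEF arrays.

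H3K4me3 in MEFs against ES cells shows which promoters carry the active mark in one cell type alone. Among promoters on the prepared lists, 18 of 35 of the fibroblast list were higher in MEFs and 15 of 29 of the pluripotency list were lower. Col3a1, a fibrillar collagen gene, had log2 ratios of 2.47 and 3.47 in MEF1 and MEF2 and of -0.52 and -0.71 in E14 and V6.5, a difference of 3.58 (adjusted p = 0.000235, n = 2 lines per group, limma, chromosome 1, 45544532 to 45550746). At Pou5f1 the ratios were -0.44 and -0.56 in the MEF lines and 1.93 and 2.47 in the ES lines, a difference of -2.70 (adjusted p = 0.000282, chromosome 17, 33601969 to 33609544). In limma, 801 of 15174 promoters were called, 315 higher and 486 lower in MEFs. This balance turned with all probes (910 and 677) and with normexp (2525 and 985).

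Also higher in MEFs were Fgf7, a growth factor made by mesenchyme (3.45), Ctsk, the protease cathepsin K (3.42), Dlc1 (3.11), Ogn, a matrix proteoglycan (3.06), Srpk2 (2.99), Il1rl1 (2.93) and Casp12 (2.92). Also lower were Trap1a (-3.27), Slc9b1 (-3.22), Zfp42 (-2.80), Dppa4 (-2.80), Cyct (-2.73), Pramel13 (-2.60) and Tdgf1, a co-receptor of Nodal signalling (-2.58). Adjusted p for these promoters lay between 0.000202 and 0.000933. Pramel13 belongs to a family of similar copies and is uncertain.

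Fibroblast promoters gained H3K4me3 in MEFs in 18 of 35 members and lost it in 0 (28 adjusted over the list alone, adjusted p = 3.7e-31, adjusted p = 0.392 with an estimated correlation, median 0.90). Col5a2 differed by 2.59, Postn by 2.49, Acta2, smooth muscle actin, by 2.44 and Col1a1 by 2.02. Pluripotency promoters were lower in 15 of 29 and higher in 0 (22 adjusted over the list alone, adjusted p = 1.13e-22, adjusted p = 0.434 with an estimated correlation, median -1.08), with Gdf3 at -2.42 and Dnmt3l at -2.24. Epithelial promoters were lower in 10 of 13 (13 adjusted over the list alone, adjusted p = 7.15e-12, adjusted p = 0.392 with an estimated correlation), with Cldn4 at -1.57 and Cdh1 at -1.11. Germ line promoters were lower in 4 of 12 (7 adjusted over the list alone, adjusted p = 8.64e-07, adjusted p = 0.392 with an estimated correlation), with Hormad1 at -1.75. Interferon promoters were higher in 4 of 12 (5 adjusted over the list alone, adjusted p = 0.000154, adjusted p = 0.392 with an estimated correlation), with Irf7 at 1.74.

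Trophoblast promoters were lower in 2 of 10 members (6 adjusted over the list alone, adjusted p = 0.000225, adjusted p = 0.451 with an estimated correlation), with Plet1 at -2.51. Hox promoters as a list were higher, with 1 of 31 called higher and 1 lower (12 adjusted over the list alone, adjusted p = 0.00169, adjusted p = 0.47 with an estimated correlation), Hoxa9 at 1.70 and Hoxc13 at -0.94. Of the reprogramming factors, 1 of 4 was lower (2 adjusted over the list alone, adjusted p = 0.0126, adjusted p = 0.47 with an estimated correlation). Adjusted p was 0.065 for the X inactivation centre, 0.204 for chromatin genes and extraembryonic endoderm, 0.286 for neural genes, and 0.451 for blood, cell cycle and imprinted genes. It was 0.46 for developmental regulators, 0.539 for housekeeping genes (median -0.05, mean 0.05) and 0.83 for cell cycle inhibitors and p53 targets. Without MEF2 186 promoters were called, with the highest 3 neighbouring probes 247 and with normexp 3510.

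For H3K4me3 in iPS cells against MEFs, 166 promoters were called in limma, 88 higher and 78 lower in iPS cells. The balance depended on scaling, with 264 higher and 1324 lower under normexp and 1072 and 269 after division by the median absolute deviation. Trap1a (3.72, adjusted p = 0.00253), Tdgf1 (3.05, adjusted p = 0.00541), Dppa4 (3.03), Pou5f1 (2.92) and Zfp42 (2.69) were higher, as were Slc9b1 (3.06), Rnf125 (2.97) and Pramel13 (2.51). Ctsk (-2.74, adjusted p = 0.00444), Ogn (-2.49), Aspn, a matrix protein (-2.38), Postn (-2.35) and Col3a1 (-2.33, adjusted p = 0.0207) were lower, as were Rgs4 (-2.50), Cc2d2a (-2.40) and Dlc1 (-2.36). The iPS ratio of Col3a1 was 0.64, above both ES lines and below both MEF lines.

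Fibroblast promoters were lower in iPS cells in 5 of 35 members (22 adjusted over the list alone, adjusted p = 5.93e-21, adjusted p = 0.394 with an estimated correlation). Pluripotency promoters were higher in 10 of 29 (16 adjusted over the list alone, adjusted p = 1.37e-20, adjusted p = 0.394 with an estimated correlation). Epithelial promoters were higher as a list with 0 of 13 called (9 adjusted over the list alone, adjusted p = 2.89e-07, adjusted p = 0.394 with an estimated correlation). Germ line promoters were higher in 2 of 12 (4 adjusted over the list alone, adjusted p = 6.4e-07, adjusted p = 0.394 with an estimated correlation), and those of the X inactivation centre in 2 of 5 (2 adjusted over the list alone, adjusted p = 0.000291, adjusted p = 0.394 with an estimated correlation). The trophoblast list (0 of 10 called, 3 adjusted over the list alone, adjusted p = 0.00082, adjusted p = 0.442 with an estimated correlation) and the reprogramming factors (1 of 4, 2 adjusted over the list alone, adjusted p = 0.0043, adjusted p = 0.442 with an estimated correlation) were higher. Interferon promoters were lower, in 1 of 12 (3 adjusted over the list alone, adjusted p = 0.0158, adjusted p = 0.394 with an estimated correlation). The other lists did not pass: adjusted p was 0.0682 for extraembryonic endoderm, 0.319 for developmental regulators and neural genes, 0.485 for Hox, 0.495 for imprinted genes and 0.582 for chromatin genes. It was 0.875 for cell cycle inhibitors, 0.88 for cell cycle and housekeeping genes and 0.976 for blood. Without MEF2 6 promoters were called, without V6.5 595 and with the highest 3 neighbouring probes 0.

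For H3K4me3 in iPS against ES cells, limma called 0 promoters, with 215 at an unadjusted p under 0.05. Among promoters that differed consistently between ES and MEF lines, the largest positive differences were at Fgf7 (1.40), Pi15 (1.27), Col3a1 (1.25), Ifi211 (1.13), Rbms3 (1.1), Ccdc80 (1.04) and the microRNA genes mmu-mir-199a-2 (1.01) and mmu-mir-125b-1 (1.00). The largest negative differences were at Plet1 (-1.26), Fgd4 (-0.95), Slc44a2 (-0.90), Slc22a18 (-0.89), Neurod1 (-0.89), Ckmt1 (-0.82), Naa11 (-0.72) and Lsr (-0.69). At each of these promoters the iPS value lay between both ES lines and both MEF lines, and the adjusted p was 1.

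As lists with 0 called members, also when adjusted over the list alone, fibroblast promoters had more H3K4me3 in iPS cells (median 0.19, adjusted p = 1.49e-06, adjusted p = 0.986 with an estimated correlation). So did Hox promoters (median 0.21, adjusted p = 0.000129, adjusted p = 0.975 with an estimated correlation) and interferon promoters (median 0.29, adjusted p = 0.00524, adjusted p = 0.707 with an estimated correlation). The X inactivation centre did as well (median 0.35, adjusted p = 0.000868, adjusted p = 0.707 with an estimated correlation), but relative to all promoters its median went from 0.39 to -0.42 with normexp. Epithelial promoters had less (median -0.24, adjusted p = 0.00324, adjusted p = 0.986 with an estimated correlation). Pluripotency promoters did not pass as a list (median -0.05, adjusted p = 0.964). Adjusted p was 0.453 for blood, chromatin, developmental regulator, extraembryonic endoderm and housekeeping genes, 0.508 for cell cycle genes and reprogramming factors, 0.626 for trophoblast, 0.628 for germ line and 0.832 for cell cycle inhibitors and p53 targets. It was 0.902 for neural genes and 0.964 for imprinted genes, and the median and mean of these had opposite signs. Without E14 6 promoters were called and without V6.5 3.

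Both ES lines differed from both MEF lines by at least 1 log2 unit at 364 promoters for H3K4me3, 171 higher and 193 lower in MEFs, a balance that turned with normexp (223 and 84) and with all probes (111 and 76). The crossed splits of the 4 lines gave 9 and 0. At 350 of the 364 the iPS value lay nearer ES cells (96.2%, exact binomial 95% interval 93.6 to 97.9). The median position, with MEF at 0 and ES at 1, was 0.757 at promoters higher in MEFs and 0.862 at promoters lower in MEFs. The share was 96.3% and 96% on the array parts.

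**Figure D2:**
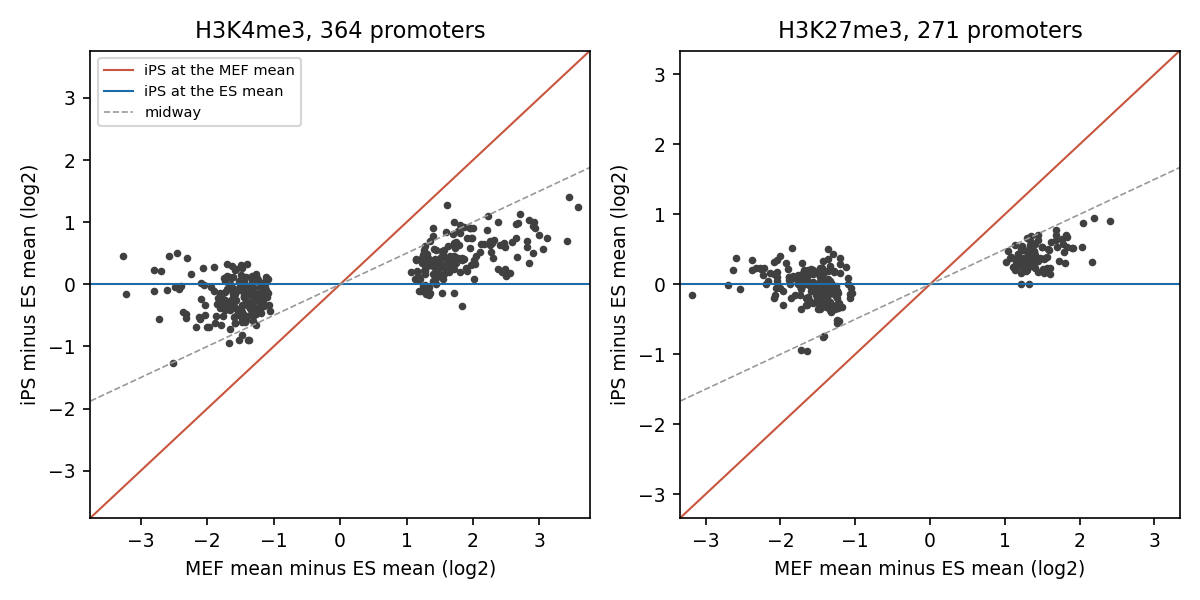
iPS minus ES mean (vertical axis, log2 units) against MEF mean minus ES mean (horizontal axis, log2 units) for the promoters that differed consistently between ES and MEF lines, 364 for H3K4me3 and 271 for H3K27me3, with lines for iPS at the ES mean, at the MEF mean and midway. One point is one promoter, and 96.2% and 97.8% of the points lay nearer the ES mean.

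H3K27me3 in MEFs against ES cells asks which promoters the Polycomb mark covers in each cell type. MEFs had less of it at 15 of 35 promoters of the fibroblast list, more at 1, and more at 12 of 29 promoters of the pluripotency list. Prrx1, a homeobox gene of limb and connective tissue mesenchyme, had log2 ratios of 2.06 and 3.08 in E14 and V6.5 and of -0.45 and -0.76 in MEF1 and MEF2 (difference -3.18, n = 2 lines per group, limma). Tdgf1 had 1.96 and 2.62 in the MEF lines and 0.04 and -0.27 in the ES lines (difference 2.40). In limma, 1871 promoters were called, 703 higher and 1168 lower in MEFs, and this balance turned with 3 neighbouring probes (1272 and 914) and with normexp (788 and 747).

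Sall4, a zinc finger factor of the pluripotency network (2.19), Arid3b (2.16), Grb7 (2.05), Mpzl2 (2.03), Lin28b, a regulator of let-7 microRNAs (1.91), Npvf (1.90) and Cldn14 (1.83) were also higher in MEFs. Zeb2, a repressor of E-cadherin (-2.70), the axon guidance gene Sema3a (-2.54) and the protocadherin genes Pcdhb19 (-2.63), Pcdhb20 (-2.59), Pcdhb3 (-2.38), Pcdhb13 (-2.38) and Pcdhb5 (-2.33) were lower. Protocadherin genes of this cluster have similar copies, so their single values are uncertain. Adjusted p for these promoters was 0.026, and 0.027 for Mpzl2.

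Fibroblast promoters had less H3K27me3 in MEFs in 15 of 35 members and more in 1, Lum (30 adjusted over the list alone, adjusted p = 8.39e-09, adjusted p = 0.952 with an estimated correlation, median -0.71). Col1a2 differed by -1.81, Snai2 by -1.77 and Col1a1 by -1.50. Pluripotency promoters had more in 12 of 29 and less in 0 (20 adjusted over the list alone, adjusted p = 8.81e-10, adjusted p = 0.952 with an estimated correlation, median 0.51), with Eras at 1.39, Pou5f1 at 1.12 and Sox2 at 1.01. Epithelial promoters had more in 6 of 13 and less in 0 (8 adjusted over the list alone, adjusted p = 1.21e-05, adjusted p = 0.952 with an estimated correlation, median 0.63), with Cdh1 at 1.28. Hox promoters did not pass as a list (1 of 31 called higher, adjusted p = 0.992), nor did developmental regulators (0 of 47 called, adjusted p = 0.377). Yet 4 of the 31 Hox promoters differed by at least 2-fold toward less of the mark in MEFs and 0 toward more. None of the 4 was called, and the mean of the list was -0.14.

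The adjusted p was 0.0522 for germ line, 0.116 for interferon, 0.286 for the reprogramming factors, 0.311 for the X inactivation centre, 0.423 for extraembryonic endoderm and trophoblast and 0.582 for chromatin genes. It was 0.767 for imprinted genes, 0.885 for blood (median -0.24, tested higher), 0.903 for housekeeping genes, 0.974 for cell cycle inhibitors and 0.992 for cell cycle and neural genes. Medians and means had opposite signs for extraembryonic endoderm, chromatin, housekeeping, cell cycle inhibitor and neural genes, and the Hox list tested higher with a median of -0.01. Without MEF2 or without V6.5 limma called 0 promoters, with 2526 and 4550 at an unadjusted p under 0.05. The turned sign of the MEF arrays reversed the direction.

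For H3K27me3 in iPS cells against MEFs, limma called 0 promoters, with 3063 at an unadjusted p under 0.05. The largest positive differences were at Prrx1 (3.03, adjusted p = 0.0995), Pcdhb20 (2.96, adjusted p = 0.0885), Pcdhb19 (2.84), Pcdhb13 (2.73), Zeb2 (2.70, adjusted p = 0.101), Pcdhb3 (2.60), Pcdhb5 (2.56) and Pcdhga5 (2.49). The largest negative differences were at Arid3b (-1.85, adjusted p = 0.1), Mpzl2 (-1.50), Tdgf1 (-1.49, adjusted p = 0.115), mmu-mir-106a (-1.49), Mpzl3 (-1.47), Lin28b (-1.39), mmu-mir-19b-2 (-1.39) and Npvf (-1.37). As lists, fibroblast promoters had more in iPS cells (21 of 35 adjusted over the list alone, median 0.63, adjusted p = 9.57e-08, adjusted p = 0.968 with an estimated correlation). Interferon promoters had more as well (4 of 12 adjusted over the list alone, median 0.38, adjusted p = 0.0264, adjusted p = 0.968 with an estimated correlation). Pluripotency promoters had less (13 of 29 adjusted over the list alone, median -0.45, adjusted p = 1.63e-09, adjusted p = 0.968 with an estimated correlation), as did epithelial promoters (1 of 13 adjusted over the list alone, median -0.43, adjusted p = 0.00119, adjusted p = 0.968 with an estimated correlation).

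The remaining lists did not pass between iPS cells and MEFs: adjusted p was 0.119 for germ line, 0.231 for the reprogramming factors, 0.475 for chromatin genes, developmental regulators and the X inactivation centre, and 0.537 for imprinted genes and trophoblast. It was 0.79 for cell cycle inhibitors, 0.804 for cell cycle and neural genes, 0.831 for housekeeping genes, 0.863 for blood and extraembryonic endoderm and 0.869 for Hox. The test direction of chromatin, developmental regulator, cell cycle, neural, housekeeping and extraembryonic endoderm genes differed from the sign of their median or mean. Without E14 or without V6.5 232 promoters were called.

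For H3K27me3 in iPS against ES cells, limma called 0 promoters, with 299 at an unadjusted p under 0.05. The largest positive differences, all at promoters higher in MEFs, were at Sall4 (0.95), Tdgf1 (0.91), Grb7 (0.87), Ttll6 (0.77), Ppp1r14d (0.71), Ckmt1 (0.71), Slc26a3 (0.70) and Sdr9c7 (0.69). The negative differences were led by Shf (-0.95), the Wnt secretion factor gene Wls (-0.94), Defb11 (-0.76), Nmi (-0.74), D3Wsu161e (-0.56), Olfr1497 (-0.53), Olfr1339 (-0.51) and Mmp16 (-0.39), all at promoters lower in MEFs. The adjusted p of each was 1. As lists with 0 called members, also when adjusted over the list alone, epithelial promoters (median 0.29), pluripotency promoters (median 0.18) and blood promoters (median 0.20) had more in iPS cells. Their adjusted p was 0.000363, 0.000363 and 0.0318, and for each the adjusted p = 0.962 with an estimated correlation.

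Fibroblast promoters had a median of -0.05 (adjusted p = 0.108). Adjusted p was 0.147 for extraembryonic endoderm and interferon genes, 0.15 for germ line, 0.459 for cell cycle, 0.498 for the reprogramming factors and 0.71 for cell cycle inhibitors. It was 0.739 for chromatin, neural, trophoblast and X inactivation genes, 0.855 for developmental regulators, Hox and imprinted genes and 0.893 for housekeeping genes, whose mean of 0.04 was opposite to the test.

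For H3K27me3, 271 promoters differed consistently between both ES and both MEF lines, 90 higher and 181 lower in MEFs, and the crossed splits gave 0 and 0. With normexp 82 were higher and 57 lower, and after division by the median absolute deviation 72 and 583. At 265 of the 271 the iPS value lay nearer ES cells (97.8%, exact binomial 95% interval 95.2 to 99.2). After that division, 69.4% of the promoters higher in MEFs lay nearer ES cells. The median position was 0.693 at promoters higher in MEFs and 0.982 at promoters lower in MEFs. The share was 95.9% and 99.3% on the array parts. Both iPS parts were scanned in a batch with an ES line and without a MEF line, so nearness and batch cannot be told apart here. Across 15174 promoters, iPS values correlated at 0.946 and 0.939 with E14 and V6.5 and at 0.755 and 0.748 with MEF1 and MEF2 for H3K27me3, and at 0.969, 0.965, 0.909 and 0.915 for H3K4me3. Promoters are not independent replicates.

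Promoters that carry both marks are a feature of pluripotent cells, in which many developmental regulators are kept silent but poised. Both marks were found at 133 promoters in E14, 767 in V6.5, 454 in iPS cells, 106 in MEF1 and 250 in MEF2. Of the 124 promoters with both marks in both ES lines, 115 had both in iPS cells (92.7%, exact binomial 95% interval 86.7 to 96.6). In MEF1 33 of them had both marks (26.6%, 19.1 to 35.3) and in MEF2 44 (35.5%, 27.1 to 44.6). These shares depended on processing: after division by the median absolute deviation they were 78.5% in iPS cells, 10.5% in MEF1 and 6.99% in MEF2, and with 3 neighbouring probes 94.7%, 43.8% and 50.4%. In both MEF lines, 45 kept H3K4me3 alone, 28 H3K27me3 alone and 31 both.

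Of the lists, 4 of 31 Hox promoters (Hoxa4, Hoxb4, Hoxc5 and Hoxc12) and 4 of 47 developmental regulators (Gata6, Isl1, Lhx9 and Sox17) were among the 124, and all had both marks in iPS cells. Of the Hox genes, 2 carried H3K27me3 alone in both MEF lines and 1 both marks. Prrx1 had H3K4me3 of 1.46 and H3K27me3 of 2.06 in E14, 1.86 and 2.42 in iPS cells, and 3.72 and -0.76 in MEF2, so that H3K4me3 alone was left in MEFs. Sox17, a regulator of endoderm, had 1.29 and 1.85 in E14, 1.18 and 2.48 in iPS cells, and 0.34 and 2.84 in MEF2, so that H3K27me3 alone was left. Gata3, a trophoblast and lymphoid regulator, carried H3K4me3 alone in both MEF lines, and the imprinted gene Grb10 both marks. The extraembryonic endoderm gene Dab2 had 2.31 and -0.48 in MEF1. The E14 H3K27me3 arrays had a narrow range, and after division by the median absolute deviation the count in E14 came near that in V6.5 (531 and 575). A limit of 0.58 log2 units raised the count in every line, to 1212 in E14 and 2182 in V6.5, so it does not bear on that range.

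**Figure D3:**
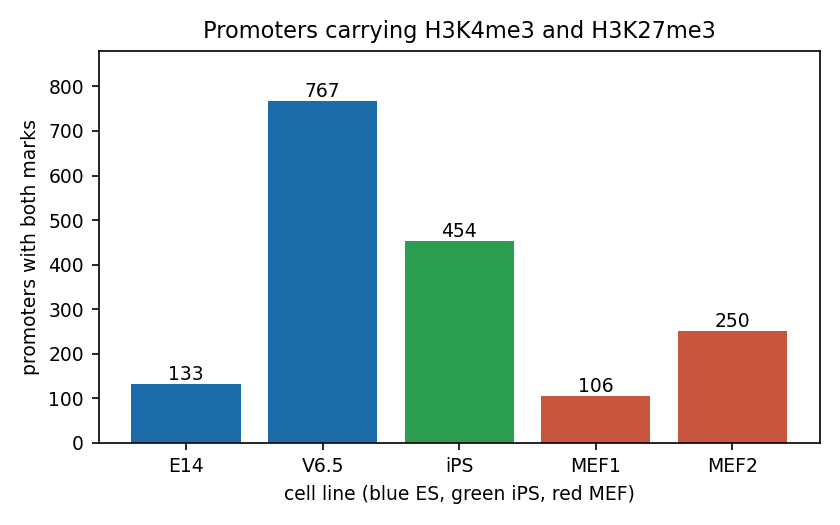
Number of promoters with a log2 ratio of at least 1 for both H3K4me3 and H3K27me3 (vertical axis) in each of the 5 lines (bars). The counts were 133 in E14, 767 in V6.5, 454 in iPS cells, 106 in MEF1 and 250 in MEF2.

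The X chromosome differed between the MEF lines, one labelled male and one female. The inactive X chromosome of female cells carries H3K27me3. In the female line MEF2, X-linked promoters had 0.712 log2 units more H3K27me3 than autosomal promoters (percentile 100 among random autosomal lists, 533 X-linked promoters), and in the male line MEF1 0.01 more (percentile 69.2). The values were 0.001 in E14, -0.006 in V6.5 and -0.027 in iPS cells (percentile 14.8). With normexp the value of E14 became -0.069 and that of V6.5 -0.037. For H3K4me3, X-linked promoters lay at -0.229 in E14, -0.236 in V6.5, -0.212 in MEF1 and -0.351 in MEF2 relative to autosomal promoters, and at -0.012 in iPS cells (percentile 42.2). One line of each sex gives no replicate of the sex difference.

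**Figure D4:**
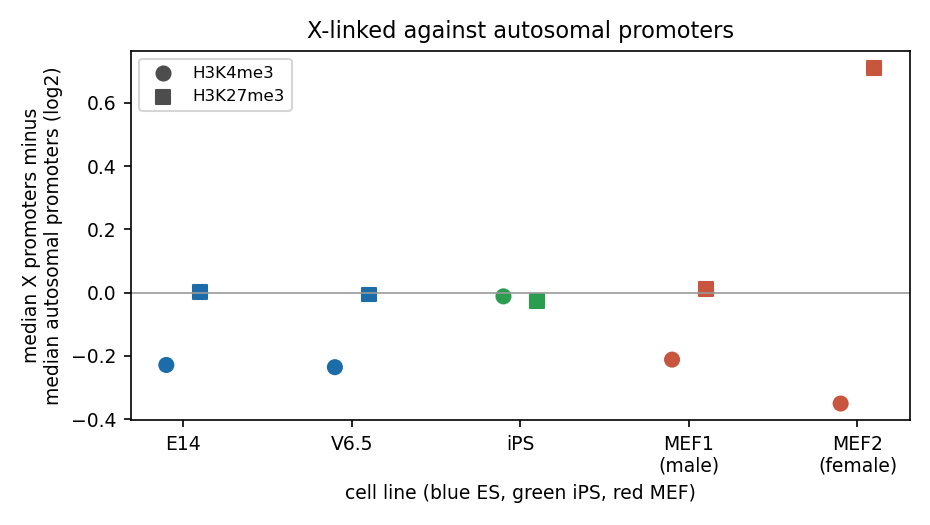
Median log2 ratio of X-linked promoters minus that of autosomal promoters (vertical axis) for each line and mark. H3K27me3 of MEF2 lay at 0.712, and the other lines lay between -0.027 and 0.01.

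Marks and expression changed together between MEFs and ES cells. Of 133 genes with consistently higher H3K4me3 in MEFs, 96.2% had higher expression in MEFs (median 3.9), and of 139 with lower H3K4me3, 16.5% did (median -2.51). Of 43 genes with consistently higher H3K27me3 in MEFs, 14% had higher expression (median -3.4), and of 131 with lower H3K27me3, 91.6% did (median 2.93). Only genes kept on the expression arrays enter. They stand for 133 of 171 and 139 of 193 promoters for H3K4me3, and for 43 of 90 and 131 of 181 for H3K27me3. Genes dim in all groups are thus left out. The share higher in MEFs over all genes was not computed for comparison, and the expression arrays hold V6.5 and female MEFs alone. Across 11094 genes, which are not independent replicates, the difference in expression correlated with that in H3K4me3 (Pearson r = 0.409, Spearman rho = 0.329) and with that in H3K27me3 (r = -0.351, rho = -0.3). Across 15174 promoters the differences in the marks correlated at r = -0.385 (rho = -0.371). These are the 3 relations computed.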

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

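Of the tests below, that of X-linked expression was written before its result was seen, and the other 6 were chosen only after the results they bear on were seen.

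At promoters with more of a mark in MEFs, iPS cells lay between ES cells and MEFs, with median positions of 0.757 for H3K4me3 and 0.693 for H3K27me3 (MEF at 0, ES at 1). A scan batch shared with a MEF line is argued against: on the array parts scanned without a MEF line the medians lay between 0.654 and 0.739, and on the part scanned with MEF2 at 0.771. The parts without a MEF line were scanned in a batch with an ES line, so nearness to ES cells there cannot be told apart from the batch. At promoters lower in MEFs the H3K4me3 median was 0.798 on the part scanned with MEF2 and 0.921 on the other part. A narrower range of the iPS arrays as a whole would bring the medians to 1 once each array is divided by its median absolute deviation. At the same promoters they were then 0.697 (bootstrap 95% interval 0.669 to 0.733) and 0.581 (0.549 to 0.639), which argues against it as the sole source. For H3K27me3 the deviations of the iPS arrays (0.417 and 0.422) lay below those of the MEF arrays (0.509 to 0.712). Division thus draws positive iPS ratios toward MEFs, so the fall from 0.693 says nothing further. At the 53 H3K4me3 promoters below -0.3 in both ES lines, the median was -0.04 in iPS and -0.57 in ES cells. Of these, 10 iPS values lay above 0.3. Low ratios drawn to the array centre could give many of these values, and compression of high or of low ratios alone was not tested. Fibroblast chromatin mixed into the iPS sample cannot be told apart. Yet in the expression arrays, a separate sample, Lum was at least 697-fold and Dcn 605-fold below MEFs. The MEF share on the linear scale was 13.1% for H3K4me3 (bootstrap 95% interval 12 to 15.1) and 20% for H3K27me3 (17.1 to 22.8), a ratio of 1.52. One share would give equal values only if the ratios of both marks had the same range, and the range differed between arrays. The labels also do not state that both marks came from one preparation. Marks of a fibroblast state that remained through reprogramming, if the iPS line came from fibroblasts, may also give these values, which was not tested.

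The fibroblast list was lower in iPS than in ES arrays, and the labels call the ES line feeder-dependent, which means that it is grown on fibroblasts. The excess of ES over iPS signal was a median 3.44% of the MEF signal over 35 list members (bootstrap 95% interval 1.68 to 5.13), 9 of them saturated in MEFs. Fibroblasts like the assayed MEFs in the ES culture are argued against as the source of all of that excess. The values are those of 10 genes at least 238-fold lower in iPS cells than in MEFs, with Dcn also among the 35 members. That limit was set from the lower end of the list's interval, which uses the ES arrays. Given the limit, the genes were picked on iPS against MEF alone. Their median ES level, or bound on it, was 0.46% of the MEF level (0.32 to 1.24), with Saa3 at 0.11%, Lum at most 0.20% and Dcn at 0.32%. For 43 genes at least 100-fold lower it was 1.40% (1.09 to 1.61), and 28 of the 43 lay below the list's interval. The excess over 20 genes outside the list, high in MEFs and not well above background in iPS cells, was a median 0.85% (0.1 to 1.8). Of these 20, 16 were higher in ES arrays, and the interval overlaps that of the list, so a smaller share stays open. That share, and fibroblasts unlike the assayed MEFs, were not tested. Extraembryonic endoderm cells in the ES culture cannot be told apart from a difference between iPS and ES cells themselves, since the 9 of 11 members of that list that were higher in ES than in iPS arrays restate the difference of the list.

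X-linked genes were higher in iPS than in ES arrays, and a candidate explanation is more than 1 active X chromosome in the iPS cells. Over 385 X-linked genes well above background in both, the median of iPS minus ES was 0.94 log2 units above that of autosomal genes (percentile 100 among random autosomal lists), 84.9% of X-linked and 45.5% of autosomal genes were higher in iPS cells, and in female MEFs against ES cells the shift was 0.02. X-linked promoters had 0.192 log2 units more H3K4me3 in iPS than in ES cells relative to autosomal promoters (percentile 100). With all probes of a gene the value was 0.097 and with normexp 0.179. These are ratios over input, and the iPS input itself held more X signal (0.399 against male MEF1). They therefore do not measure the number of X copies or of active X chromosomes. Xist lay at -0.36 in iPS cells, -4.69 in ES cells and 3.33 in MEFs. A second copy alone is argued against at 20 of the 509 X-linked genes tested, the 12 called ones among them, which rose by more than 2-fold (one-sided test of each gene in limma's fit, adjusted over the 509). The labels give no sex or origin of the iPS line, the ES lines are known as male, and one iPS line cannot separate its sex from its reprogramming.

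In the input channel, which no comparison uses by itself, X chromosome probes of the iPS H3K4me3 arrays lay at 0.4 log2 units and Y chromosome probes at -1.47 relative to male MEF1, against 0.419 and -1.913 in female MEF2. On the iPS H3K27me3 arrays the input values were 0.4 for the X and -1.16 for the Y chromosome, against 0.546 and -1.157 in MEF2. In E14 and V6.5 the X values on the H3K4me3 arrays were -0.013 and 0.041 and the Y values -0.205 and 0.226. The iPS input thus lay near that of the female line and apart from both ES lines, which goes with a second X copy in the iPS chromatin. The expression arrays are a separate sample. In the incomplete expression scanner file filed under the iPS duplicate, which no comparison uses, Pou5f1 had a log2 signal of 13.6. Xist had 3.65 in that file, against 9.233 in the value table column of the same sample and 3.861 and 4.602 in the ES columns.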

How the results depend on the processing

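Array weights, the scanner files as filed, the ES and iPS arrays alone, and the position and the lists without the MEF duplicate array were chosen after seeing the data. For the changes below the cause was not tested, except that leaving out arrays or lines changes the spread of the shared fit, and lone samples are then assumed to vary like the other groups. For promoter arrays no paired analysis was possible because each cell line belongs to one cell type. The labels of the expression arrays give no numbers that match across groups, and those arrays were fitted with the slide as a block. The scan date as a block was not run, since the expression arrays share one date. Normexp and the slide block ran without the iPS duplicate array, which lacks a matching scanner file. The low share of probes well above background on most expression arrays limits what is seen of dim genes.

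In expression, MEF against ES gave 3233 calls without a filter on dim probes, 3185 with array weights, 3942 with the scanner files as filed, where the direction was reversed, and 2551 to 9746 with each array left out. iPS against ES gave 113 with normexp, 21 with quantile normalisation, 0 without the filter, 26 with the mean over probes, 137 with the slide block (122 higher, 15 lower), 2651 as filed, 3156 with array weights (1534 higher, 1622 lower), 2859 (1408 higher, 1451 lower) from the ES and iPS arrays alone, and 0 to 2859 with each array left out. iPS against MEF gave 3776 without the filter, 2327 with the slide block, 11 as filed, and 2695 to 9759 with each array left out. The share of genes nearer ES cells was 90.6% with normexp, 90.4% with quantile normalisation, 75.3% and 76.1% where genes were chosen on one set of arrays and measured on the other, and 85.7% without the MEF duplicate array.

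For H3K4me3, MEF against ES gave 1587 calls with all probes (910 higher, 677 lower), 247 with 3 neighbouring probes (125 and 122), 3510 with normexp (2525 and 985), 2033 after division by the median absolute deviation (551 and 1482), and 186 to 905 with each line left out. iPS against ES gave 0 with normexp, where the differences correlated negatively with those reported, 4 after division, 3 without V6.5, and 0 to 6 with each line left out. iPS against MEF gave 517 with all probes (224 higher, 293 lower), 0 with 3 neighbouring probes, 1588 with normexp (264 and 1324), 1341 after division (1072 and 269), 595 without V6.5, and 6 to 595 with each line left out. The consistent difference was found at 187 promoters with all probes (111 higher, 76 lower), 791 with 3 neighbouring probes (350 and 441) and 1027 at 0.58 log2 units (381 and 646), where a split of one ES and one MEF line against the others gave up to 271 and 394. The share nearer ES cells was 93.3% with 3 neighbouring probes, 92.2% with normexp (75% at promoters lower in MEFs), 91.7% after division (83.5% at promoters higher in MEFs), and 91.7% with promoters chosen on V6.5 and MEF2.

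For H3K27me3, MEF against ES gave 3663 calls with all probes (1256 higher, 2407 lower), 5215 after division (1548 and 3667), 0 without V6.5, 10012 with the MEF sign turned, where the direction was reversed, and 0 to 1871 with each line left out. iPS against MEF gave 700 with all probes (609 higher, 91 lower), 2793 after division (2373 and 420), 232 without V6.5, 8652 with the sign turned, again reversed, and 0 to 232 with each line left out. The consistent difference was found at 1003 promoters with 3 neighbouring probes (432 higher, 571 lower), 139 with normexp (82 and 57), 655 after division (72 and 583), 1320 at 0.58 log2 units and 3110 with the sign turned, where such a split gave up to 7 with 3 neighbouring probes and 44 at 0.58 log2 units. The share nearer ES cells was 93.0% with 3 neighbouring probes, 95% after division, 94.8% at 0.58 log2 units, 100% with the sign turned and 90.2% with promoters chosen on V6.5 and MEF2. At promoters higher in MEFs alone it was 69.4% after division and 75.4% with that choice.

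Promoters with both marks at 0.58 log2 units and with 3 neighbouring probes numbered 1212 and 3255 in E14, 2182 and 4059 in V6.5, 1815 and 4137 in iPS cells, 648 and 2442 in MEF1, and 977 and 2941 in MEF2. After division they numbered 531 in E14 and 67 in MEF2. Of the promoters with both marks in both ES lines, 78.5% had both in iPS cells after division. In MEF1 the share was 43.8% with 3 neighbouring probes and 10.5% after division, and in MEF2 50.4% and 6.99%. The X chromosome against autosomes was -0.096 for H3K4me3 in MEF1 with all probes, weaker than before, and with normexp -0.069 for H3K27me3 in E14, reversed, and -0.037 in V6.5, past the random lists. The marks correlated at -0.446 with all probes. With an estimated correlation 0 lists passed for expression in MEF against ES, iPS against ES and iPS against MEF, and 0 in these comparisons of H3K4me3 and of H3K27me3.

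Values of named genes kept their side of the threshold in 619 cases under alternatives that keep all arrays, lost their call in 58 and gained one in 31. With arrays or lines left out they kept it in 747 cases, lost it in 108 and gained one in 17. The turned sign and the scanner files as filed are not among these cases. Some cases could not differ. For expression the deposited values are those of the main fit, and leaving out the lone iPS line leaves MEF against ES unchanged for both marks (32 cases). Gene lists kept it in 109 cases and lost it in 53, each with an estimated correlation. Without the MEF duplicate array the Hox list lost its call in iPS against ES expression (adjusted p = 0.0616), and the trophoblast list gained one in MEF against ES (0.00148) and iPS against MEF (0.0012).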

Other observations

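Of the tests below, the X-linked share of the genes called in iPS against ES cells and the values of genes outside the naming rule were chosen after the results were seen.

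Lists that did not move as a whole held members that did between MEFs and ES cells. Among imprinted genes, the neighbouring genes H19 and Igf2 were 18.8-fold and 12.6-fold higher in MEFs and Peg3 7.63-fold. Among cell cycle inhibitors and p53 targets, Cdkn2b was 7.28-fold, Cdkn2a 4.02-fold and Cdkn1a, the gene of p21, 2.93-fold higher, and Perp, a junction gene, 22-fold lower. Among developmental regulators, the mesenchymal genes Osr1 and Tbx15 were 35.8-fold and 23.9-fold higher and Tbx5 at least 17-fold, while Pax6, a regulator of eye and brain, was at least 8.59-fold lower and Foxa2, a regulator of endoderm, at least 5.05-fold. Tfap2c and Plet1 of the trophoblast list were 84.3-fold and 26.9-fold lower, with the MEF arrays far apart (SD 2.24 and 2.16). Of the neural list, Nes was 6.45-fold lower and Ncam1, a cell adhesion gene, 7.55-fold higher. B2m, a housekeeping gene that is also part of antigen presentation, was 9.46-fold higher and Hprt 4.97-fold lower. At the X inactivation centre, Tsix, the antisense partner of Xist, was 4.32-fold and Rlim, an activator of Xist, 3.76-fold lower. Of the reprogramming factors, Klf4 was at least 2.83-fold lower (adjusted p = 0.082) and Myc differed by 0.46 (adjusted p = 0.601).

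Promoters of developmental regulators moved in both directions in H3K4me3: Lhx9 (1.45), Osr1 (1.26) and Tbx5 (1.01) were higher in MEFs, and Neurod1 (-1.39) and Sox17 (-1.03) lower. H3K27me3 was lower in MEFs at Cd14, a macrophage receptor (-1.34), at the Polycomb gene Bmi1 (-1.56) and at Irf7 (-0.85), and higher at the complement gene C1qb (0.88).

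Of the genes called higher in iPS than in ES cells, 12 of the 22 with a chromosome in the annotation lay on the X chromosome, against 509 of 14129 tested genes (odds ratio 32.9, Fisher's exact test, two-sided p = 1.96e-12). Of these, 5 belong to the Xlr, Mage and Prame families. Genes are not independent replicates, and near-identical copies in these families may share signal. The p-value takes neither this nor the shift of X-linked genes as a whole into account. None of the 6 called lower with a chromosome lay on the X. Called genes outside the naming rule, named after their values were seen, included Wdfy4 (at least 10.3-fold higher), the chemokine Ccl3 (at least 4.72-fold), Cox7b2 (at least 3.87-fold), and, as log2 differences, Gbp2b (3.85), Aass (3.75), Sp110 (3.19) and Pdlim3 (3.19). The shift of X-linked genes between iPS and ES cells was 0.94 without the called genes and these families, 0.94 with normexp and 0.95 with quantile normalisation.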
